A study of Homo sapiens with 53 samples.

How the data were processed

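The study measured polyadenylated RNA in 53 libraries of A431 cells. Per the labels, libraries were made from total RNA with the QuantSeq FWD kit for 3′ tags, and cells were lysed after 48 to 72 h with or without ASO; which time applies to which library, the mode of delivery and the ASO sequences are not given in the sources used here. Samples were grouped by experiment, ASO and concentration as the labels state them, which gave 22 groups.

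The deposited tables give 1 library each, with estimated counts of reads per transcript that need not be whole, per the file headers; the names of the tables say that reads were deduplicated. The submitters' processing notes name STAR, featureCounts, UMI-tools 1.1, Salmon 0.7.2 and the build GRCh38, without their roles or order. A TPM column stood beside the estimated counts and was not used, because it divides by transcript length, which does not bear on reads taken from 3′ ends. The annotation release is not given in the sources used here. The tables list 228297 transcripts in experiment 1 and 273426 in experiment 2, of which 97.6% and 80.1% matched GENCODE version 29 or its table of symbols. The reads of unmatched transcripts, 0.525 to 0.667% of a library in experiment 1 and 4.65 to 5.15% in experiment 2, were left out. A gene whose reads went to unmatched transcripts is therefore too low in experiment 2, which leaves levels not comparable between the experiments; each change is against the no-ASO libraries of the same experiment. Estimated counts were summed per gene (56486 and 56316 genes, 56307 in both) and rounded to whole numbers. Symbols are current gene names, and coordinates are from GENCODE version 29 on GRCh38.

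Totals were 1767925 to 3744737 reads per library, and 13084 to 16597 genes had at least 1 read. At this depth 1 CPM is about 2 to 4 reads in a library, so single libraries say little about genes near 1 CPM. All 73 pairs of replicates were compared by a chi-square test over genes with at least 20 reads; 0 pairs agreed within sampling noise (chi-square per degree of freedom 2.54 to 13.0), so no pair was treated as a repeat deposit of 1 library. This test does not show that libraries came from separate cultures, since preparation alone also adds spread.

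Tests, bands, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Band contrasts used edgeR 4.0.16 quasi-likelihood F-tests (R 4.3.3) with TMM scaling, filterByExpr and a Benjamini-Hochberg FDR under 0.05. All libraries of an experiment shared 1 estimate of the spread, and a band was the mean of its concentration groups minus the no-ASO group. The trend was a slope on log10 concentration over the treated libraries alone. The difference between ASOs was the difference of the high-band contrasts in a fit of all 53 libraries. CPM values use TMM library sizes. Curves had 4 parameters (log-logistic) and were fitted with scipy 1.17.1 (Python 3.11.15, numpy 2.4.6, pandas 2.3.3) to log2(CPM + 0.5), with intervals from 1000 bootstraps of residuals; the half-maximal concentration is where the fitted curve crosses 0.5 of its no-ASO level. Figures were drawn with matplotlib 3.10.9.

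Of 33 gene lists, 28 had at least 3 tested members with the ACTN1 ASO and 27 with the control ASO. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, again with an estimated correlation, and with fry. Over both ASOs 28 calls were made with the preset correlation, 18 with an estimated one and 37 with fry, which asks only whether a list moved. Untested were the actinin family (ACTN1, ACTN4), fibroblast, endothelial, neural and blood cell markers and, with the control ASO, hepatocyte markers. A list level per library is the mean log2 ratio of its members to the no-ASO libraries.

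Named genes were the measured actinin genes; for each ASO, the 10 largest rises and the 10 largest falls of the high band among genes at an FDR under 0.05, with at least 5 CPM in the higher group and all high-band libraries on 1 side of the no-ASO mean; for the difference, the 5 largest each way under the same FDR and CPM rule; the 5 lowest half-maximal concentrations with an interval inside the tested range; and up to 4 members of each list with the smallest p, as examples. Genes without a symbol were not named, and a few genes that meet the rule are not reported here. Other named genes are said to be chosen after their values were seen.

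Alternatives were library totals and DESeq2 size factors in place of TMM, no expression filter, a filter at 5 CPM, a fit of the band and the controls alone, DESeq2 1.42.0, a 2-fold minimum, the trend without 20 µM or with the no-ASO libraries, curves with a fixed slope or bottom, experiments fitted separately, and each library left out in turn. Chosen after seeing the data were the high band without 20 µM, a filter of 5 CPM in both experiments, and thinning of all libraries to the smallest total. For each count, 40 splits of the libraries of an experiment (30 for the difference) were drawn, the real one included.

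Each step was tested on simulated data, with counts drawn from the real means and library sizes and a seeded set of genes changed by known folds. For the ACTN1 ASO high band (11270 genes), 61.5% of genes changed 1.5-fold, 83.1% of those changed 2-fold and 98.5% of those changed 4-fold were recovered, and for the control ASO high band (9454 genes) 40.0%, 84.6% and 96.9%. Recovery at 2-fold was 88.1% and 72.7% in the middle and low bands of the ACTN1 ASO (11252 and 11246 genes), 72.3% and 80.3% in those of the control ASO (9452 and 9419 genes), 66.7% and 73.8% for the trends (10316 and 8682 genes) and 66.0% for the difference (9436 genes). False calls were 4 to 12 per step. Of 30 unchanged lists 0 were called, and all 100 simulated curves gave a half-maximal concentration within 2-fold of the truth. Simulated genes varied independently, so the list result does not cover genes that vary together. Every simulated curve fell to 0 with a slope of 1, so curves of other shapes were not covered.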

Results

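RNA was measured in 53 libraries of A431 cells, a human epidermoid carcinoma line with keratinocyte features, by sequencing of short tags from the 3′ ends of polyadenylated RNA. The cells received an antisense oligonucleotide (ASO), a short synthetic strand that pairs with a target RNA, or none. Experiment 1 used an ASO against ACTN1, the gene of the actin crosslinking protein alpha-actinin-1, and experiment 2 a non-targeting control ASO. Each ASO was given at 10 concentrations in 2.5-fold steps up to 20 µM, for 48 to 72 h per the labels. Experiment 1 held 8 libraries without ASO and 17 with the ACTN1 ASO. There was 1 library each at 0.0052, 0.0328 and 0.0819 µM and 2 at every other concentration. Experiment 2 held 8 libraries without ASO and 20 with the control ASO. Concentrations were grouped into a low band (up to 0.0328 µM), a middle band (0.0819 to 1.28 µM) and a high band (3.2, 8 and 20 µM). They held 4, 7 and 6 libraries of the ACTN1 ASO and 6, 8 and 6 of the control ASO. Library totals were 2378037 to 3744737 reads in experiment 1 and 1767925 to 3407278 in experiment 2. Mitochondrially encoded genes took 14.6% ± 0.832 (SD, n = 25) of the reads in experiment 1. In experiment 2 they took 24.5% ± 2.09 (SD, n = 8) without ASO and 27.8% ± 0.852 (SD, n = 6) in the high band. The labels do not say that replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

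The first question was how far the ACTN1 ASO lowered its target. ACTN1 (chromosome 14, 68874143 to 68979440, GRCh38) stood at 238.5 ± 17 CPM (reads scaled to library size; SD, n = 8) without ASO in experiment 1 and at 6.52 ± 1.42 CPM (SD, n = 6) in the high band. Its level fell to 79.8% of the no-ASO mean at 0.0052 µM (1 library) and to 63.9% ± 12.1 (SD, n = 2) at 0.0131 µM. It was 37.5% at 0.0328 µM (1 library), 16.2% at 0.0819 µM (1 library) and 6.18% ± 0.782 (SD, n = 2) at 0.2048 µM. From 0.512 µM on, the mean of each concentration lay between 2.68% and 3.33% of the no-ASO mean, and single libraries between 1.84% and 3.69%. The high-band log2 fold change was -5.18 (SE 0.11, adjusted p = 2.69e-19, edgeR quasi-likelihood test). ACTN4, the other actinin gene measured, had a log2 fold change of -0.02 (SE 0.09, adjusted p = 0.917). With the control ASO, ACTN1 was at 18.5 ± 5.92 CPM (SD, n = 8) without ASO and at 19.4 ± 3.73 CPM (SD, n = 6) in the high band. The log2 fold change was 0.05 (SE 0.21, adjusted p = 0.940), and ACTN4 changed by 0.21 (SE 0.15, adjusted p = 0.483). The level of ACTN1 cannot be set side by side between the experiments, because their tables list different sets of transcripts. The change of 0.05 with the control ASO may cover only part of the gene's reads.

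**Figure D1:**
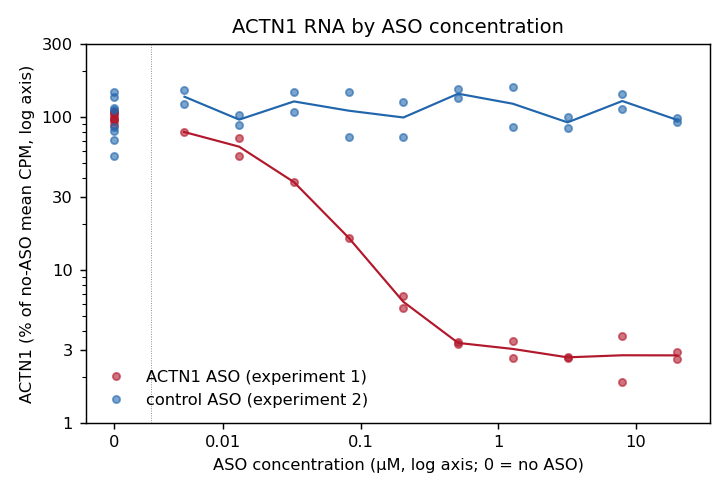
ACTN1 level as percent of the mean of the no-ASO libraries of the same experiment (log axis) against ASO concentration in µM (log axis, 0 for no ASO); points are libraries and lines join the means of each concentration. The ACTN1 ASO brought ACTN1 to a mean of 6.18% at 0.2048 µM and to means between 2.68% and 3.33% from 0.512 µM on, while means with the control ASO lay between 92.2% and 141.9%.

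A curve fitted to all 25 libraries put the half-maximal concentration for ACTN1 at 0.0222 µM, with a 95% bootstrap interval of 0.0170 to 0.0284 µM, and left 2.68% of the fitted no-ASO level at the top concentration. The fitted slope was 1.44. Fixing the slope at 1 gave 0.0119 µM, below that interval. At 0.0131 µM the 2 libraries were still at 55.4% and 72.4% of the no-ASO mean, so this value does not match them. Fixing the bottom at 0 gave 0.00269 µM. That lies below the lowest concentration tested, 0.0052 µM, where ACTN1 was still at 79.8% of the no-ASO mean, so that curve misses the data there.

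The next comparison asked which other genes changed at high concentrations of the ACTN1 ASO. Of 11606 genes tested, 822 were higher and 903 lower in the high band than without ASO, 97 and 95 of them at least 2-fold. CHAC1, a glutathione-degrading enzyme induced under amino acid or ER stress, rose from 8.41 ± 3.05 CPM (SD, n = 8) to 50.6 ± 7.98 CPM (SD, n = 6), a log2 fold change of 2.57 (SE 0.15, adjusted p = 1.93e-11). The stress-induced chromatin protein gene NUPR1 rose by 2.10 (adjusted p = 7.78e-13) and the stress cytokine gene GDF15 by 1.83 (adjusted p = 2.00e-11). DDIT3, which encodes the transcription factor CHOP, rose by 1.80 (adjusted p = 9.03e-07) and the stanniocalcin gene STC2 by 1.70 (adjusted p = 3.98e-09). The secretoglobin gene SCGB1A1 rose by 2.21 (34.5 to 166 CPM, adjusted p = 1.20e-11) and the immunoglobulin transporter gene PIGR by 2.27 (1.05 to 5.31 CPM, adjusted p = 1.23e-05). The clusterin gene CLU rose by 1.82 (35.2 to 131 CPM, adjusted p = 2.38e-13) and the iron-siderophore-binding LCN2 by 1.72 (20.2 to 66.7 CPM, adjusted p = 7.34e-10). ELF3-AS1 (log2 fold change 1.76, adjusted p = 4.54e-05) is antisense to another gene, and its reads are uncertain because the use of strand in counting is not given in the sources used here.

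Under the rule for named genes, the falls in the high band included those of MB21D2, INTS2 and EXOC6B. MB21D2 went from 6.26 ± 1.84 CPM (SD, n = 8) to 0.370 ± 0.254 CPM (SD, n = 6), a log2 fold change of -4.07 (SE 0.38, adjusted p = 7.39e-08). INTS2, a subunit of the Integrator complex, went from 6.33 to 0.428 CPM, a change of -3.79 (SE 0.40, adjusted p = 3.65e-07). EXOC6B, an exocyst subunit gene, changed by -2.94 (29.5 to 3.8 CPM, adjusted p = 3.48e-11). LRRC59, whose product sits in the ER membrane, changed by -2.56 (81.3 to 14 CPM, adjusted p = 3.69e-15) and NHLRC2 by -2.34 (25.5 to 5.05 CPM, adjusted p = 8.45e-11). LRRC59 was also called lower in the high band of the control ASO, so its fall was not particular to the ACTN1 ASO. The Polycomb-related SCMH1 changed by -2.33 (11.9 to 2.46 CPM, adjusted p = 1.47e-07) and the kinase gene MAPK10, which encodes JNK3, by -2.20 (5.33 to 1.18 CPM, adjusted p = 2.72e-05). GTF3C3, a subunit of the RNA polymerase III factor TFIIIC, changed by -2.26 (adjusted p = 0.00560). Its libraries overlapped, at 0.90 to 10.7 CPM without ASO and 0 to 5.25 CPM in the high band. The pseudogene SUMO2P1 (log2 fold change -6.64, adjusted p = 0.0130) shares sequence with its parent gene and is uncertain. Its call was lost without the 20 µM libraries (adjusted p = 0.0560, range over alternatives 3.45e-41 to 0.0560). Of all 11606 genes tested, 567 had no overlap between the 6 high-band and 8 no-ASO libraries, where chance gives 0.0333% of genes in each direction. Library totals in place of TMM moved the split from 822 and 903 to 595 higher and 1309 lower, and DESeq2 called 506 and 560. The high band without the 20 µM libraries gave 521 and 512.

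Gene lists fixed beforehand moved in groups under the ACTN1 ASO. Of 23 measured members of the integrated stress response list, targets of the transcription factor ATF4, 19 rose and 0 fell, 20 and 1 adjusted over the list alone, with a median log2 fold change of 0.99 (camera adjusted p = 2.94e-49). Besides CHAC1, GDF15 and NUPR1, the cystine transporter gene SLC7A11 rose by 1.06. Of 26 hypoxia and glycolysis genes, 24 fell and 0 rose, the same counts adjusted over the list alone, with a median of -0.67 (adjusted p = 1.09e-52). The hypoxia-induced NDRG1 changed by -1.44, the glucose transporter gene SLC2A1 by -1.19, the lactate dehydrogenase gene LDHA by -1.02 and the phosphoglycerate kinase gene PGK1 by -1.01. Of 25 cholesterol synthesis genes 10 fell and 1 rose (10 and 2 adjusted over the list alone, median -0.33, adjusted p = 8.99e-05). HMGCS1 changed by -0.92, INSIG1 by -0.68 and MSMO1 by -0.60. Of 38 cytosolic ribosomal protein genes 18 rose and 0 fell (19 and 0 adjusted over the list alone, median 0.17, adjusted p = 1.48e-06). RPL4 rose by 0.34 and RPL5 by 0.31, although pseudogenes share sequence with this family. Of 36 nuclear genes of oxidative phosphorylation 12 fell and 0 rose (13 and 0 adjusted over the list alone, median -0.18, adjusted p = 1.18e-05). ATP5MC1 changed by -0.57 and COX8A by -0.50.

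Of 19 keratinocyte differentiation genes 7 fell and 1 rose with the ACTN1 ASO (8 and 2 adjusted over the list alone, median -0.30, adjusted p = 9.42e-05). The cornified envelope gene SPRR1B changed by -0.72 and the desmosomal DSC2 by -0.48. KRT6A (-0.98) and KRT6B (-0.86) are near-identical to each other and uncertain. Of 15 basal keratinocyte and hemidesmosome genes 7 fell and 1 rose (8 and 1 adjusted over the list alone, median -0.24, adjusted p = 0.00125). The basal keratin gene KRT5 changed by -0.82 and the laminin-332 gene LAMB3 by -0.44, against a rise of 0.78 for the dystonin gene DST. Replication-dependent histones fell in 6 of 10 and rose in 0 (7 and 0 adjusted over the list alone, median -0.69, adjusted p = 0.00388). H1-2 stood at -0.49 and H2AC6 at -1.18, though members of this family share sequence and are uncertain. The libraries took polyadenylated RNA, so these counts speak only for polyadenylated histone transcripts. G2 and mitosis genes fell in 5 of 28 (0 rose; the same adjusted over the list alone, median -0.13, adjusted p = 0.00419). The proliferation marker gene MKI67 changed by -0.34 and TPX2 by -0.26. In the list of the ER unfolded protein response 4 of 18 fell and 1 rose (8 and 1 adjusted over the list alone, median -0.20, adjusted p = 0.00412). The ER chaperone gene HSPA5 changed by -0.40, SDF2L1 by -0.55 and CRELD2 by -0.51, against 0.38 for HERPUD1. Targets of SRF and MRTF rose in 7 of 18 and fell in 2 (9 and 2 adjusted over the list alone, median 0.21, adjusted p = 0.00388). CCN1 stood at 0.85 and the cytoplasmic actin gene ACTG1 at 0.36 against -0.51 for the tropomyosin gene TPM4 and -0.41 for TAGLN2.

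For p53 targets the median was -0.01, the mean 0.18 and the test upward (adjusted p = 0.00614), with 3 of 20 higher and 3 lower, also adjusted over the list alone. The pro-apoptotic BBC3 rose by 1.19 and SESN2 by 1.07, while CDKN1A, the cell cycle inhibitor p21, changed by -0.32. SESN2 is also on the integrated stress response list, so the calls of these lists overlap. The activity of p53 was not measured. Interferon-stimulated genes rose in 7 of 33 and fell in 2 (10 and 2 adjusted over the list alone, median 0.20, adjusted p = 0.0128; adjusted p = 0.0555 with an estimated correlation). OASL rose by 1.77 and HERC5 by 1.28. YAP and TAZ targets rose in 4 of 17 (0 fell; the same adjusted over the list alone, median 0.07, adjusted p = 0.0161; adjusted p = 0.104 with an estimated correlation). No-ASO replicate 2 of experiment 1 stood apart on this list (-0.25, others -0.04 to 0.08) and is part of its baseline. All other calls of the ACTN1 ASO held with an estimated correlation. No call was made for focal adhesion and actin crosslinking genes (3 higher and 9 lower of 34, adjusted p = 0.392), NF-kB and inflammatory genes (0 and 3 of 12, 0.0802) or heat shock genes (1 and 6 of 17, 0.0802). The same held for mesenchymal genes (2 and 1 of 10, 0.0802), EGFR and MAPK response genes (6 and 1 of 24, 0.0750), nuclear-retained long noncoding RNAs (3 and 0 of 8, 0.0885) and phosphorothioate-binding nuclear proteins (5 and 1 of 19, 0.0988). Lysosomal genes (4 and 3 of 31, 0.118), S phase genes (0 and 2 of 22, 0.235), metallothioneins (1 and 1 of 5, 0.392) and mitochondrially encoded genes (2 and 2 of 15, 0.427) did not pass either. No call was made for NRF2 targets (3 and 2 of 21, adjusted p = 0.635; median -0.10, mean -0.00, test upward) and for apoptosis regulators (2 and 2 of 20, adjusted p = 0.126; median -0.04, mean 0.11, test upward). Markers of other cell types were sparse: 7 hepatocyte genes gave an adjusted p of 0.0552, and LUM rose by 1.37 and CDH5 by 2.74, both at low levels (1.41 to 4.16 and 0.412 to 3.51 CPM). COL1A1 stood at 0.02, MAP2 at -0.03 and MBP at 0.08, and no blood cell marker was tested. With library totals the lower genes went from 4 to 7 in the ER unfolded protein response and from 5 to 9 in G2 and mitosis. They went from 12 to 18 in oxidative phosphorylation and from 0 to 1 in the integrated stress response. Without the 20 µM libraries, lower genes went from 5 to 2 in G2 and mitosis, 12 to 5 in oxidative phosphorylation, 7 to 4 in keratinocyte differentiation, 3 to 1 among p53 targets and 2 to 0 among interferon-stimulated genes, and higher genes from 18 to 9 among ribosomal proteins, 7 to 4 among interferon-stimulated genes and 1 to 0 in the ER unfolded protein response.

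At lower concentrations the number of genes called with the ACTN1 ASO depended on the expression filter. In the middle band 6 genes were higher and 23 lower with the filter and 61 and 114 without it. With the filter, 0 and 11 of them changed at least 2-fold, and 409 and 666 genes had an unadjusted p under 0.05. ACTN1 changed by -4.14 (adjusted p = 3.85e-18), MB21D2 by -2.70 (adjusted p = 1.45e-05), and EXOC6B by -1.47 (adjusted p = 7.53e-07). MAPK10 changed by -1.42 (adjusted p = 0.0188), LRRC59 by -1.39 (adjusted p = 6.88e-11), NHLRC2 by -1.36 (adjusted p = 6.29e-07) and SCMH1 by -1.14 (adjusted p = 0.00318). INTS2 changed by -2.28, HTT, the huntingtin gene, by -0.93, the thymidylate kinase gene DTYMK by -0.71, OCRL by -0.75 and HMGCS1 by -0.47. CLU rose by 0.40, and the other genes that rose were PRSS23 (0.46), SLC39A4 (0.36), KRT17 (0.34), AMIGO2 (0.31) and ZSWIM6 (0.84). These 5 and HTT, DTYMK and OCRL were chosen after their values were seen. In the low band ACTN1 was the 1 gene lower (-0.79, adjusted p = 2.44e-04) and the pseudogene FABP5P7 the 1 gene higher (adjusted p = 0.00665), with 296 higher and 393 lower genes at an unadjusted p under 0.05 and 0 and 3 by DESeq2. With no expression filter the low band gave 43 higher and 58 lower genes, and a fit of this band and the controls alone gave 2 lower. FABP5P7 shares reads with its parent gene and is uncertain, at 0 to 1.2 CPM without ASO and 46.9 to 207.8 CPM in the low band. The middle-band counts depended on single libraries. Leaving out the 0.0819 µM library gave 35 and 51 higher and lower genes, no-ASO replicate 2 gave 3 and 15, replicate 4 gave 3 and 13, replicate 5 gave 1 and 14 and replicate 7 gave 2 higher. Leaving out 0.2048 µM replicate 1 gave 3 higher and replicate 2 gave 2 and 15, 0.512 µM replicate 1 gave 2 and 12, and 1.28 µM replicates 1 and 2 gave 1 and 2 higher. In the low band 2 genes were higher without no-ASO replicate 3 or 6, 2 lower without no-ASO replicate 3 or 5, and 0 lower without the 0.0328 µM library. Library totals gave 11 higher in the middle band and a filter at 5 CPM gave 10, and library totals moved the share of higher genes there from 20.7% to 32.4%.

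**Figure D2:**
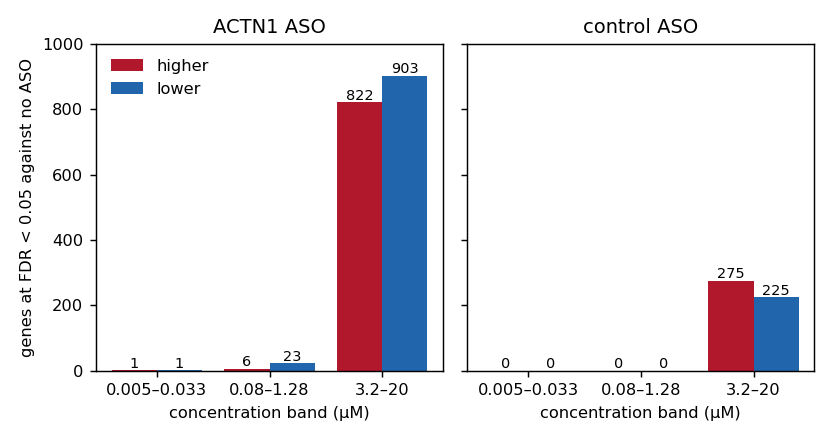
Number of genes higher (red) and lower (blue) than in the no-ASO libraries at an FDR under 0.05, by concentration band in µM, for the ACTN1 ASO (left) and the control ASO (right). The high band gave 822 and 903 genes with the ACTN1 ASO and 275 and 225 with the control ASO, against at most 23 in any lower band.

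Across the 17 libraries of the ACTN1 ASO alone, 535 of 10394 genes rose and 473 fell with log10 concentration, 173 and 98 of them at least 2-fold over the range tested. ACTN1 fell by 1.74 on the log2 scale per 10-fold concentration (adjusted p = 1.20e-09), EXOC6B by 1.0, LRRC59 by 0.86, NHLRC2 by 0.83 and MAPK10 by 0.78. CHAC1 rose by 0.93, SCGB1A1 by 0.87, PIGR and NUPR1 by 0.83 each and GDF15 by 0.81. Without the 20 µM libraries 246 genes rose and 229 fell, and without replicate 1 at 20 µM alone the count of rising genes was 342. Adding the no-ASO libraries gave 733 falling genes.

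Curves were fitted to the 46 other genes that fell with concentration and were at least 2-fold lower in the high band, to say at which concentrations they fell. Of these, 36 had an interval within the tested concentrations, with a median half-maximal concentration of 3.01 µM, 135 times that of ACTN1. Genes that fall only near the top concentration could hardly enter by the 2-fold rule, so this median partly reflects the choice of genes. In 34 of the 36 the interval lay above that of ACTN1. Among genes with a symbol and a fitted curve, the lowest were MAPK10 at 0.143 µM (0.0172 to 0.563), whose interval overlapped that of ACTN1, and EXOC6B at 0.174 µM (0.0983 to 0.277). They were followed by NHLRC2 at 0.194 µM (0.116 to 0.293), LRRC59 at 0.215 µM (0.123 to 0.343) and SCMH1 at 0.220 µM (0.0783 to 0.475). MB21D2 and INTS2 had too few reads in the treated libraries to be tested in the trend and so got no curve. In the middle band they stood at 15.4% ± 13.6 and 20.1% ± 11.6 of the no-ASO mean, against 37.1% ± 6.54 for MAPK10 and 35.8% ± 17.3 for EXOC6B (SD, n = 7). Genes of the hypoxia and glycolysis list fell at much higher concentrations, NDRG1 at 3.34 µM, SLC2A1 at 4.15 µM, PGK1 at 6.88 µM and LDHA at 7.68 µM. For curves still falling at 20 µM, the concentration is where the fitted curve crosses 0.5 of its no-ASO level, not the middle of a completed response.

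**Figure D3:**
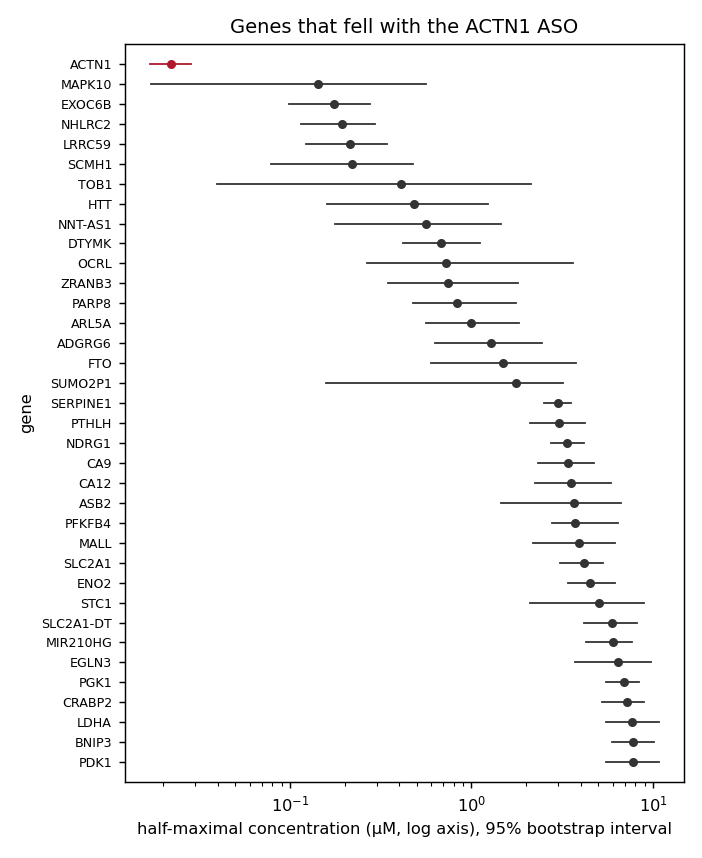
Half-maximal concentration in µM (log axis) with its 95% bootstrap interval for ACTN1 (red) and for the genes with a symbol that fell with the ACTN1 ASO and whose interval lay within the tested concentrations (black). ACTN1 sits lowest at 0.0222 µM, followed by MAPK10 at 0.143 µM, while LDHA sits at 7.68 µM.

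The control ASO series asked what a non-targeting ASO changes at the same concentrations. In the high band 275 of 9680 genes were higher and 225 lower than without ASO, 35 and 12 of them at least 2-fold. NLRP7, a member of the NOD-like receptor family, rose from 5.64 ± 1.51 CPM (SD, n = 8) to 19.5 ± 5.94 CPM (SD, n = 6), a log2 fold change of 1.75 (SE 0.19, adjusted p = 4.65e-06). The short-chain fatty acid receptor gene FFAR2 rose by 1.57 (5.30 to 16.3 CPM, adjusted p = 1.00e-05) and the lysyl oxidase-like LOXL4 by 1.57 (3.70 to 11.3 CPM, adjusted p = 5.40e-04). The interferon-induced GTPase gene GBP2 rose by 1.42 (10.5 to 29.3 CPM, adjusted p = 6.63e-06). VTCN1 (1.53), PIK3IP1 (1.46), TP53INP2 (1.41), PIGR (1.40), RNASE7 (1.33) and YPEL3 (1.31) rose at adjusted p-values between 0.00974 and 0.0255. PLCB1, a phospholipase C gene, changed by -1.64 (7.80 to 2.57 CPM, adjusted p = 0.00239) and the kinase gene MAPK12 by -1.04 (8.38 to 4.07 CPM, adjusted p = 0.00578). HSPA5 changed by -1.67 (adjusted p = 0.00228), but its levels were 0 to 77.3 CPM over the 6 high-band libraries and 77.2 to 132 CPM without ASO. Its mean without ASO was 107 CPM here and 983 CPM in experiment 1, so this change may cover only part of the gene's reads and is uncertain. Smaller falls were called for the amino acid transporter gene SLC7A5 (-0.99), the lipoic acid synthase gene LIAS (-0.96), MTARC1 (-0.96) and SH3D21 (-0.89), at adjusted p-values of 0.0296 to 0.0470. NOMO3 was called as well (-1.07, adjusted p = 0.0380), but it shares reads with its copies and is uncertain. Of these genes PIK3IP1, TP53INP2, PIGR, RNASE7, NOMO3, SLC7A5, LIAS, MTARC1 and SH3D21 lost their call when 1 library was left out, each for at least 3 of the 14 libraries. VTCN1 and YPEL3 lost theirs without the 20 µM libraries, and NLRP7, FFAR2, LOXL4, GBP2, PLCB1 and MAPK12 kept it under every alternative. The high band without the 20 µM libraries gave 109 higher and 60 lower genes, and no expression filter gave 356 lower. Leaving out 3.2 µM replicate 1 gave 143 lower genes, and library totals moved the split from 275 and 225 to 216 higher and 319 lower.

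Several lists moved under the control ASO, some opposite to the ACTN1 ASO. Cholesterol synthesis genes rose in 14 of 23 and fell in 0 (16 and 0 adjusted over the list alone, median 0.62, adjusted p = 3.02e-27). The synthase gene HMGCS1 rose by 0.95, INSIG1 by 0.92, MSMO1 by 0.88 and the squalene epoxidase gene SQLE by 0.68. Integrated stress response genes fell in 9 of 17 and rose in 0 (11 and 0 adjusted over the list alone, median -0.47, adjusted p = 4.07e-13). SESN2 stood at -0.67, STC2 at -0.64, the serine synthesis gene PSAT1 at -0.63 and SLC7A11 at -0.47. NF-kB and inflammatory genes rose in 6 of 13 (0 fell; the same adjusted over the list alone, median 0.45, adjusted p = 3.10e-05). BIRC3 rose by 0.96, the inhibitor gene NFKBIA by 0.55 and CXCL1 by 0.50. Interferon-stimulated genes had 1 of 23 higher and 0 lower (4 and 0 adjusted over the list alone, median 0.29, adjusted p = 9.07e-05). Lysosomal genes rose in 3 of 28 and fell in 0, also adjusted over the list alone (median 0.14, adjusted p = 5.03e-04). NEU1 rose by 0.73, NPC2 by 0.40 and PSAP by 0.27. Nuclear-retained long noncoding RNAs fell in 2 of 8 (0 rose; 4 and 0 adjusted over the list alone, median -0.74, adjusted p = 3.42e-04). Its examples GAS5 (-0.83) and SNHG1 (-0.68) are snoRNA host transcripts, so the call may not speak for RNAs kept in the nucleus. Where these RNAs reside was not tested. These 6 calls held with an estimated correlation and those that follow did not. Without the 20 µM libraries higher genes went from 14 to 9 in cholesterol synthesis and from 1 to 0 among interferon-stimulated genes, and lower genes from 9 to 4 in the stress response and from 2 to 1 among the noncoding RNAs. Library totals also left 0 higher interferon-stimulated genes.

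Mitochondrially encoded genes were higher in 5 of 15 (8 adjusted over the list alone, median 0.22, adjusted p = 2.57e-07; adjusted p = 0.126 with an estimated correlation), and with them the mitochondrial share of the reads. No-ASO replicate 5 of this experiment stood apart on this list (-0.51, others -0.02 to 0.12) and on the mitochondrial share (19.7%, others 23.9 to 25.9%), and it is part of the baseline for this rise. Nuclear genes of oxidative phosphorylation were lower in 3 of 36 (4 adjusted over the list alone, median -0.10, adjusted p = 0.00217; adjusted p = 0.0608 with an estimated correlation). Phosphorothioate-binding nuclear proteins were lower in 2 of 19 (3 adjusted over the list alone, adjusted p = 0.0130; adjusted p = 0.126 with an estimated correlation), and the same replicate stood at -0.64 on that list (others -0.05 to 0.07). Ribosomal protein genes were lower in 3 of 38 (3 lower and 1 higher adjusted over the list alone, adjusted p = 0.0234; adjusted p = 0.477 with an estimated correlation). Heat shock genes were lower in 1 of 16 (adjusted p = 0.0468; adjusted p = 0.126 with an estimated correlation). Hypoxia and glycolysis genes had 3 higher and 1 lower of 24 (4 and 1 adjusted over the list alone, adjusted p = 0.0215; adjusted p = 0.0855 with an estimated correlation). Metallothioneins had 1 higher of 4 (2 adjusted over the list alone, adjusted p = 0.0223; adjusted p = 0.0608 with an estimated correlation). Keratinocyte differentiation genes had 4 higher and 1 lower of 25 (adjusted p = 0.0390; adjusted p = 0.323 with an estimated correlation). Without the 20 µM libraries higher mitochondrially encoded genes went from 5 to 2, higher keratinocyte genes from 4 to 2 and lower genes from 3 to 0 in oxidative phosphorylation and from 2 to 0 among phosphorothioate-binding proteins. Higher glycolysis genes went from 3 to 1 and lower ones from 1 to 0, lower ribosomal protein genes from 3 to 1 and lower heat shock genes from 1 to 0. Library totals gave 1 higher glycolysis gene, 0 higher metallothioneins and 5 lower ribosomal protein genes. No call was made for focal adhesion genes (adjusted p = 0.213), histones (0.224), basal keratinocyte genes (0.346), G2 and mitosis genes (0.446), p53 targets (0.446) or mesenchymal genes (0.446). The same held for SRF and MRTF targets (0.523), apoptosis regulators (0.592), the ER unfolded protein response (0.593), NRF2 targets (0.766) and YAP and TAZ targets (0.798). It also held for S phase genes (0.771; median -0.01, mean -0.10, test upward) and EGFR and MAPK response genes (0.977; median and mean -0.03, test upward).

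In the middle and low bands of the control ASO, edgeR with the expression filter called 0 genes in either direction. With no filter it called 36 higher and 119 lower genes in the middle band and 22 and 96 in the low band, and with the low band and the controls alone in the fit it called 2 lower. At an unadjusted p under 0.05 there were 241 higher and 436 lower genes in the middle band and 149 and 249 in the low band, and DESeq2 called 3 and 12 in the middle band and 0 in the low band. Leaving out no-ASO replicate 8 gave 2 higher genes in the middle band. There, leaving out 0.2048 µM replicate 2 gave 2 lower and leaving out either replicate at 0.512 µM gave 1 lower. In the low band leaving out 0.005243 µM replicate 1 gave 1 lower gene and 0.032768 µM replicate 2 gave 2. Across the 20 treated libraries, 349 of 8714 genes rose and 272 fell with concentration, 77 and 18 at least 2-fold over the range. PIK3IP1 rose by 0.61, FFAR2 by 0.59, GBP2 by 0.58 and NLRP7 by 0.57 on the log2 scale per 10-fold concentration, and PLCB1 fell by 0.49. Without the 20 µM libraries 146 rose and 98 fell. Without replicate 1 at 20 µM alone the count of falling genes was 174, and library totals gave 269 rising and 391 falling.

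The last comparison tested whether the high-band response differed between the ASOs. Of 11732 genes, 504 had a higher and 428 a lower response to the ACTN1 ASO than to the control ASO, 108 and 87 of them by at least 2-fold. The difference was -5.20 on the log2 scale for ACTN1 (SE 0.26, adjusted p = 4.70e-18), -3.93 for MB21D2 (SE 0.41, adjusted p = 3.18e-09), -3.51 for INTS2 (SE 0.41, adjusted p = 6.60e-08) and -3.43 for GTF3C3 (SE 0.83, adjusted p = 0.00599). For ACTN1, with 18.5 CPM without ASO in experiment 2 against 238.5 CPM in experiment 1, the difference may rest on only part of the gene's reads in experiment 2. FABP5P7 (7.84), CTSH (4.88), EIF4H (4.61), RANBP2 (4.25), ANKRD36 (3.32) and RASA4 (-4.24) passed at adjusted p-values between 8.49e-06 and 0.0474, but each lost its call when at least 3 of the 28 libraries were left out in turn. EIF4H stood near 0 CPM in experiment 2 and FABP5P7 at 0 CPM in 3 of 6 high-band libraries of experiment 1. By list, the stress response (13 of 23 higher, adjusted p = 1.26e-45) and ribosomal protein genes (16 of 38 higher, 7.90e-12) responded higher to the ACTN1 ASO. So did the list of nuclear-retained long noncoding RNAs (4 of 8 higher, 4.26e-05), which also holds snoRNA host transcripts. Hypoxia and glycolysis genes (17 of 26 lower, 2.46e-38), cholesterol synthesis genes (16 of 25 lower, 3.90e-25) and NF-kB genes (3 of 13 lower, 1.02e-04) responded lower. The same held for keratinocyte differentiation genes (5 of 27 lower, 3.84e-04) and, by their polyadenylated transcripts, histones (3 of 12 lower, 1.72e-04). Calls for phosphorothioate-binding proteins (0.00137), mitochondrially encoded genes (0.00437) and basal keratinocyte genes (0.0229) were lost, with adjusted p = 0.0532, 0.333 and 0.0671 with an estimated correlation. Each ASO was given in 1 experiment, so the ASO and the experiment cannot be told apart in these differences. The high band without the 20 µM libraries gave 205 and 208, and library totals moved the split from 504 and 428 to 386 higher and 509 lower.

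**Figure D4:**
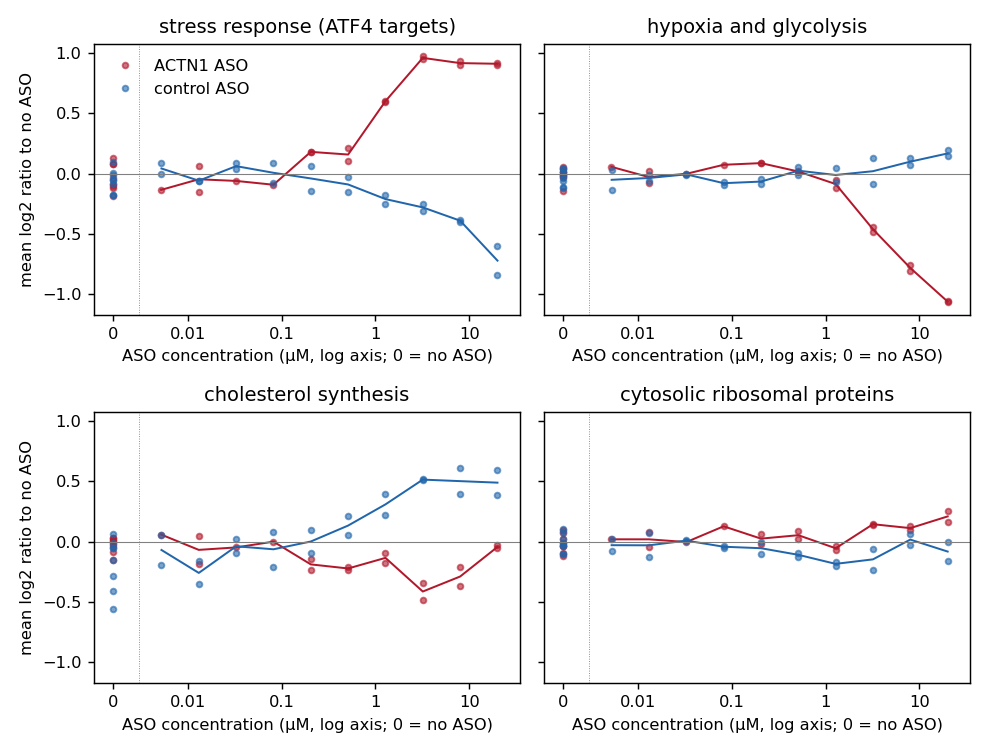
Mean log2 ratio to the no-ASO libraries of the same experiment over the members of 4 gene lists, against ASO concentration in µM (log axis, 0 for no ASO); points are libraries and lines join the means of each concentration, red for the ACTN1 ASO and blue for the control ASO. In the high band the stress response list lay at 0.93 ± 0.03 (SD, n = 6) with the ACTN1 ASO and at -0.46 ± 0.22 (SD, n = 6) with the control ASO, and the hypoxia and glycolysis list at -0.77 ± 0.27 and 0.10 ± 0.10.

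The genes called for each ASO in the high band were compared over the 9442 genes tested in both. Higher with both ASOs were 71 genes, of 719 and 263, where independent lists would share 20.0 (Fisher's exact test, p = 3.78e-22). PRSS23, CLU, LCN2, SLPI, NPC2 and TFRC were among them, of which PRSS23, SLPI and TFRC were chosen after their values were seen. Higher with the ACTN1 ASO and lower with the control ASO were 41 genes (17.1 for independent lists, Fisher's exact p = 1.14e-07), including PSAT1, SLC7A11, STC2, SESN2 and CHAC1. The reverse held for 33 genes (22.4 for independent lists, Fisher's exact p = 0.0242), including MSMO1, HMGCS1, INSIG1 and SQLE. Lower with both were 23 genes (19.1 for independent lists, Fisher's exact p = 0.332), including LRRC59, KRT5, KRT6A and HSPA5. Genes are not independent replicates, so these p-values are too small where genes move together. Across genes, the log2 fold changes of the ASOs had Pearson's r = 0.0667 and Spearman's rho = 0.0374.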

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

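The test with all libraries thinned to the smallest total, the search for sequence shared with ACTN1 RNA and the comparison of list levels within experiment 1 were chosen only after the result was seen.

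With the ACTN1 ASO in the middle band 23 genes were lower, among them ACTN1, MB21D2, EXOC6B, LRRC59, NHLRC2 and SCMH1. LRRC59 was also called lower with the control ASO in the high band. Deeper no-ASO libraries were argued against as the whole cause, since 19 of the 23 genes stayed called after all libraries were thinned to the smallest total. The genes other than ACTN1 spanned a median of 57.6 kb, against 28.7 kb in sets matched on expression (95% range 15.1 to 56.0 kb, permutation p = 0.0418 over 10000 sets), so gene length stays open as a candidate explanation, just beyond the range. Pairing of the ASO with other RNAs may also account for them: the 12-base sequence of mature ACTN1 RNA most over-represented among these 22 genes gave a permutation p of 0.295 over 1000 sets. That search covered neither introns nor the sequence of the ASO, so it decides nothing either way.

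At high concentrations of the ACTN1 ASO integrated stress response genes rose and hypoxia and glycolysis genes fell. Library totals in place of TMM left median log2 changes of 0.939 and -0.72, so the choice between these scalings did not make the pattern. That swap shifted the median of all genes by only -0.0539, so it is no wider test of scaling. Within experiment 1 the glycolysis list lay at -1.07 to -0.44 in the 6 high-band libraries and at -0.15 to 0.05 in the 8 without ASO. The stress response list lay at 0.90 to 0.97 and at -0.19 to 0.13 (exact permutation p = 0.000666 for each, two-sided, the smallest it can give). These libraries gave the list changes themselves, so this test restates them. A difference between the experiments does not enter contrasts within 1 experiment, so the test does not bear on it. Among the 10 libraries at 0.512 µM or more the glycolysis list changed by -0.72 on the log2 scale per 10-fold concentration (r = -0.988, permutation p = 3e-05, adjusted 0.00012; rho = -0.985, permutation p = 3e-05, adjusted 0.00012; r = -0.995 without the 2 libraries farthest from the median), against -0.18 for ACTN1 (r = -0.391, permutation p = 0.268, adjusted 0.306; rho = -0.394, permutation p = 0.271, adjusted 0.309; r = -0.171 without the 2 farthest). The stress response list changed by 0.46 (r = 0.845, permutation p = 0.00159, adjusted 0.00424; rho = 0.640, permutation p = 0.0568, adjusted 0.0908; r = 0.689 without the 2 farthest), which passed by r and not by rho, and 8 such relations were computed. By these slopes the level of ACTN1 RNA is unlikely to be the whole cause for the hypoxia and glycolysis list. ACTN1 was low in these libraries, at 4.38 to 8.81 CPM, so a small further fall of ACTN1 could be missed. The slopes were not tested against each other, however, and the 10 libraries are replicates at shared concentrations. For the difference of these lists between the ASOs, the ASO and the experiment cannot be told apart, because 0 ASOs were given in both.

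Higher with both ASOs in the high band were 71 genes, among them CLU, LCN2 and NPC2. Expression level of the called genes was argued against, since 10000 pairs of lists drawn within 98 bins of expression shared at most 47 genes (median 27, permutation p = 0.0001, the smallest they can give). The choice of TMM over library totals was argued against as well. Library totals left 53 shared genes of 510 and 204, where independent lists would share 11.02. A response to ASOs of any sequence may underlie part of this overlap, as a hypothesis found on these data, and genes that vary together were not tested as a source of it.

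Single libraries stood apart in 13 of 102 tests of the gap between the end value and its neighbour. Each test took 1 item over the 8 no-ASO libraries of 1 experiment. Chance alone gives about 1 in 20, but the items overlap, so the tests are not independent. No-ASO replicate 5 of experiment 2 had 19.7% mitochondrial reads (others 23.9 to 25.9%), ACTN4 at 61.3 CPM (116 to 154), the mitochondrially encoded list at -0.51 (-0.02 to 0.12) and the phosphorothioate-binding list at -0.64 (-0.05 to 0.07). Without it the control ASO high band gave 306 higher and 237 lower genes and the difference between ASOs 516 and 460. No-ASO replicate 1 of experiment 2 had 3379268 reads (others 2117398 to 2664881). NOMO3 stood at 11.4 CPM in no-ASO replicate 8 of experiment 2 (others 4.04 to 6.39). In experiment 1, MB21D2 stood at 10.4 CPM in no-ASO replicate 6 (4.52 to 6.93) and PIGR at 2.71 CPM in replicate 8 (0.544 to 1.2). The mitochondrially encoded list stood at 0.16 in replicate 6 of experiment 1 (-0.13 to -0.00) and the hypoxia and glycolysis list at -0.15 in replicate 3 (-0.03 to 0.05). In its replicate 2 the YAP and TAZ list stood at -0.25 (-0.04 to 0.08) and the phosphorothioate-binding list at -0.0766 (-0.02 to 0.03).

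Lists and genes that passed in opposite directions with the ASOs, with the difference tested, were the integrated stress response (adjusted p = 1.26e-45), hypoxia and glycolysis (2.46e-38), cholesterol synthesis (3.9e-25), ribosomal proteins (7.9e-12) and keratinocyte differentiation (0.000384). With an estimated correlation the calls of the control ASO alone were lost for hypoxia and glycolysis (adjusted p = 0.0855), ribosomal proteins (adjusted p = 0.477) and keratinocyte differentiation (adjusted p = 0.323), so their opposite direction with that ASO is not settled. Among genes the log2 difference was 3.19 for CHAC1, 2.36 for STC2, 1.76 for MTARC1 and 1.51 for SH3D21. The control ASO call of MTARC1 was lost in 11 of 21 alternatives and that of SH3D21 in 15 of 21, so their opposite direction is not settled either. The difference was 7.84 for FABP5P7, whose reads are shared with copies and uncertain.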

How the results depend on the processing

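The high band without 20 µM, the filter of 5 CPM in both experiments and the thinning of libraries were chosen only after the result was seen. No paired analysis was possible because the labels number the treated libraries in a single run over all concentrations and the no-ASO libraries apart from them, so no number marks a replicate shared by the groups compared. Of 2068 values for named genes under other settings, 1901 kept their side of the threshold, 131 fell below it and 36 passed it. With a library left out the counts were 758 and 124 of 882. For gene lists 134 of 166 were kept, 16 lost and 16 gained. No call reversed its direction. Values that passed in neither fit counted as kept whatever their direction. ACTN1 with the control ASO, for example, ranged from -0.04 to 0.16 around its main value of 0.05. Genes near 1 CPM rest on few reads in a library. Library totals shifted the median of all genes by at most 0.0539 (log2). The cause was not tested for counts that moved, except where fewer libraries or genes or a stricter threshold entered by construction.

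A change of at least 2-fold left 97 higher and 95 lower genes in the ACTN1 ASO high band, 0 and 11 in the middle band and 0 lower in the low band. It left 173 rising and 98 falling in the ACTN1 ASO trend, 35 and 12 in the control ASO high band, 77 and 18 in its trend, and 108 and 87 in the difference. With no expression filter the ACTN1 ASO gave 61 and 114 in the middle band and 43 and 58 in the low band. The control ASO then gave 356 lower in the high band, 36 and 119 in the middle band and 22 and 96 in the low band. Library totals gave 11 higher in the ACTN1 ASO middle band and 5 CPM gave 10. The share of higher genes moved with library totals from 47.7% to 31.3% in the ACTN1 ASO high band, 55.0% to 40.4% in the control ASO high band, 56.2% to 40.8% in its trend and 54.1% to 43.1% in the difference. In the ACTN1 ASO middle band it moved from 20.7% to 32.4%, to 34.9% with no filter and to 35.7% at 5 CPM. With only the band and the controls in the fit, 2 genes were lower in the low band of either ASO. The trends without the 20 µM libraries gave 246 and 229 (ACTN1 ASO) and 146 and 98 (control ASO), and adding the no-ASO libraries gave 733 falling with the ACTN1 ASO. DESeq2 gave 506 and 560 in the ACTN1 ASO high band, 0 and 3 in the low band, and 3 and 12 in the control ASO middle band. The high band without 20 µM gave 521 and 512, 109 and 60 with the control ASO, and 205 and 208 for the difference. The half-maximal concentration of ACTN1 was 0.0119 µM with the slope fixed at 1, below its bootstrap interval. With the bottom fixed at 0 it was 0.00269 µM, below the lowest concentration tested. Gene list tests gave 18 calls with an estimated correlation, against 28.

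With each library left out in turn, the ACTN1 ASO middle band ranged from 1 (no-ASO replicate 5) to 35 (0.0819 µM) higher and from 12 (0.512 µM replicate 1) to 51 (0.0819 µM) lower. The low band ranged from 1 to 2 higher (2 without no-ASO replicate 3 or 6) and from 0 (0.0328 µM) to 2 lower (no-ASO replicate 3 or 5). Rising genes of the ACTN1 ASO trend ranged from 342 (20 µM replicate 1) to 538. Lower genes of the control ASO high band ranged from 143 (3.2 µM replicate 1) to 278, and falling genes of its trend from 174 (20 µM replicate 1) to 276. The control ASO middle band ranged from 0 to 2 higher (no-ASO replicate 8) and 0 to 2 lower (0.2048 µM replicate 2), and the low band from 0 to 2 lower (0.032768 µM replicate 2). The ACTN1 ASO high band (626 to 802 and 718 to 835), the difference (376 to 516 and 341 to 460) and the ACTN1 half-maximal concentration (0.0212 to 0.0244 µM) stayed within 1.5 times, as did every count with thinned libraries and the difference at 5 CPM in both experiments.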

Other observations

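The exact test of ACTN1 in the low band was chosen only after the result was seen.

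With the control ASO, the 10 libraries at 0.512 µM or more gave further relations of the same 8. The stress response list changed by -0.36 per 10-fold concentration (r = -0.910, permutation p = 3e-05, adjusted 0.00012; rho = -0.985, permutation p = 3e-05, adjusted 0.00012; r = -0.890 without the 2 farthest libraries). Cholesterol synthesis changed by 0.23 (r = 0.750, permutation p = 0.0137, adjusted 0.0274; rho = 0.689, permutation p = 0.0371, adjusted 0.0741; r = 0.492 without the 2 farthest), so this relation leans on those libraries. Hypoxia and glycolysis changed by 0.10 and did not pass (r = 0.641, permutation p = 0.0499, adjusted 0.0798; rho = 0.739, permutation p = 0.0203, adjusted 0.0542; r = 0.730 without the 2 farthest), nor did ACTN1 at -0.25 (r = -0.445, permutation p = 0.192, adjusted 0.256; rho = -0.394, permutation p = 0.269, adjusted 0.309; r = -0.146 without the 2 farthest). Cholesterol synthesis with the ACTN1 ASO changed by 0.05 (r = 0.208, permutation p = 0.562, adjusted 0.562; rho = 0.246, permutation p = 0.509, adjusted 0.509; r = 0.289 without the 2 farthest).

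Chance was tested by 40 splits of the libraries of an experiment into groups of the same sizes, the real one included, by 40 reassignments of concentrations for each trend, and by 30 splits for the difference. Chance was argued against for the ACTN1 ASO high band, where 1 split, the real one, gave 822 higher and 903 lower genes. The highest others gave 73 and 137. These splits cannot exclude chance, since 1 of 40, or 1 of 30, is the smallest share they can give. A split that mixes treated and untreated libraries also widens the spread within its groups, which lowers its counts. In its middle band (6 and 23) the highest other gave 1 and 1, and in its trend (535 and 473) 0 and 1, again with 1 split as large. For the control ASO chance was argued against in the high band (275 and 225, highest others 0 and 1) and the trend (349 and 272, highest others 1 and 0). For the difference (504 and 428) the highest others gave 63 and 52. In the low band of the ACTN1 ASO 2 splits gave as many higher genes (1, highest other 1) and 6 as many lower genes (1, highest other 2), so by these counts chance was not excluded. A count of 1 does not test the size of a change, and the 1 lower gene was ACTN1. It lay at 37.5 to 79.8% of the no-ASO mean in the 4 low-band libraries and at 87.97 to 108% in the 8 without ASO. An exact permutation test gave p = 0.00404, two-sided, the smallest it can give. That test was chosen after the fall was seen in these same libraries, so it restates the fall and is no separate evidence against chance. For the middle and low bands of the control ASO 0 genes were found, so the splits say nothing about chance there, since each of the 40 gives at least 0; the highest others gave 0 and 2, and 2 and 5.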
